A study of Mus musculus with 2 samples.

How the data were processed

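The series holds RNA-seq of 2 samples of hair follicle stem cells sorted from mouse skin, 1 in telogen and 1 in anagen II-III. Per the labels' protocols, cells were sorted by flow cytometry as integrin alpha 6 high and CD34 positive, without SCA1 or markers of non-epidermal cells, libraries were made with an Illumina mRNA kit, and paired ends were read on an Illumina HiSeq instrument. The deposited values are TPM, a length-normalised measure of transcript abundance, per the file headers. Per the submitters' processing notes, Bowtie2 2.2.9, RSEM 1.2.30 and the mm10 genome build were used. The gene annotation and any filter are not given in the sources used here. TPM divides by gene length and by the library's total, so it keeps no read depth, and a few very abundant or very short features lower every other value. No interval or detection floor could be set on any value.

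The table has 12 columns of per-sample values. The column named 1 was taken as the anagen sample, since that sample alone has a title numbered 1. This match of a name is the only link between the values and the stage. The other 11 columns were not used. The series text says that it reanalyses samples of other series. Of these, 1 column shares its flow cell lane with the anagen column and, by elimination, could hold the telogen sample. Its name refers to Shh, which stands in the genotype of both samples, and carries no label of the telogen sample alone, so it was left out. The planned comparison of anagen with telogen, with its fold changes, its random lists matched on mean expression and its correlation of libraries, was therefore not made. What was computed instead, after the table was seen, is the level of each gene and list within 1 library. The labels do not say how many animals the library holds.

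The table has 42661 rows for 42392 gene IDs, because 160 IDs stand on more than 1 row under different symbols, always with the same value. Each ID was used once, and the values then summed to 1000000, against 1004981 over all rows. The file gives no symbol for 13933 IDs, which hold 22.4% of all TPM. A table of gene names matched 41523 IDs and supplied missing symbols. Where a symbol stood on more than 1 ID, the ID with the higher value was taken for that gene. Gene types came from a RefSeq table of assembly GRCm38.p6, matched by symbol for 32667 IDs. Positions are those of GRCm38, of which mm10 is another name. Nuclear protein-coding genes held 47.9% of TPM, protein genes of the mitochondrial genome 17.5%, and the 50 highest genes together 41.6%.

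Before the data were examined, 43 gene lists were fixed for follicle identity, lineages, other skin cells, signalling, the cell cycle, the integrated stress response, serine and one-carbon metabolism, and cell stress. For each list, the text gives members at 1 TPM or more and the median over all members. The median of the protein-coding members at 1 TPM or more was placed among 10000 random lists of the same size, drawn from all 11659 protein-coding genes at that level. A list was called high above the 97.5th and low below the 2.5th percentile. By this rule 16 of the 41 lists with at least 3 such members were high, 4 were low and 21 lay between. These percentiles describe 1 library, are not p-values, and mostly show that the chosen genes are well expressed.

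The percentile was tested on simulated lists made from the levels of these 11659 genes. With 200 genes raised 2-fold, 90% of lists of 30 and 39% of lists of 10 came out high, and with 4-fold, all lists of 30 and 81% of lists of 10. With no change, at most 2% were called high. The simulation used fewer random lists for each call and raised every member of a list by the same factor. Lists of fewer than 10 genes were not simulated, so these rates do not cover them. The genes named in the text are a panel fixed in advance, some or all members of lists of at most 10 expressed genes, and the 4 highest and the 2 lowest members of larger lists. The last part replaced a planned rule on fold changes and was chosen after the table was seen. Some members that this rule would name are not reported here. Shmt1, Mthfd1, Gdf15 and the kinases Eif2ak1 and Eif2ak2 were added after their values were seen.

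Other filters, scalings, summaries and backgrounds were tried, 2 of the backgrounds being chosen after seeing the data, and the closing section gives their effect. A position given by the mean uses the mean of the log2 TPM values in place of the median. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.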

Results

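The series profiled RNA from hair follicle stem cells, the long-lived epithelial cells of the follicle bulge that regrow the hair at each cycle. The cells came from the skin of female mice carrying a K15-CrePGR transgene, in which a Cre fused to the progesterone receptor is driven by a keratin 15 promoter, and 1 functional copy of Shh. Both samples had received RU486, the ligand that activates such a Cre, for 8 days. The titles call both samples controls. The labels place 1 sample in telogen, the resting phase of the follicle, and 1 in anagen II-III, its early growth phase. The design text implies a comparison of the 2 stages. It was not made here, because the deposited expression table has a column whose name fits the anagen sample and none whose name fits the telogen sample alone. The telogen library was not analysed here, and what follows describes the anagen library. It has no replicate, so no value carries an error and no test across animals was possible. The read depth behind the TPM values is unknown. Of 42392 genes in the table, 24251 had a value above 0, 14452 reached 1 TPM and 10347 reached 5 TPM. Among protein-coding genes, 11659 reached 1 TPM, and their median was 12.5 TPM.

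The anagen library carried the transcripts of bulge stem cells at high levels. All 23 listed bulge genes were above 1 TPM, with a median of 36.7 TPM, and this median exceeded that of 99.9% of random lists of the same size. Krt15, the keratin that marks the bulge, stood at 3364 TPM and was the 7th highest nuclear protein-coding gene. Col17a1, which anchors stem cells to the basement membrane, stood at 398 TPM, the vitamin D receptor gene Vdr at 336 TPM and Postn at 288 TPM. Among other transcription factor genes of the bulge, Lhx2 stood at 171 TPM, Sox9 at 52.1 TPM, Tcf7l1 at 36.7 TPM and Nfatc1 at 16.1 TPM. Lgr5, a receptor that marks the lower bulge and hair germ, stood at 63.9 TPM. Bmp6 and Fgf18, signals linked to quiescence, were near the bottom of the list at 8.17 and 7.02 TPM, and Cdh13 was lowest at 3.64 TPM. Genes linked to telogen quiescence as a list had a median of 28.6 TPM, above 98.8% of random lists, or 94.7% among genes at 5 TPM or more, led by the Wnt antagonist Sfrp1 at 280.3 TPM, Id3 and Txnip at 133 TPM each, and Id2 at 87.2 TPM. The lowest of that list were the cell cycle inhibitors Cdkn1c and Cdkn2b, at 2.69 and 2.07 TPM.

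Genes of the selected surface proteins were far above those of most excluded ones. Cd34 and Itga6, the surface proteins used to select the cells, stood at 132 and 99.4 TPM. Pecam1, Pdgfra, Kit and Ptprc, which encode the excluded markers CD31, CD140a, CD117 and CD45, stood at 2.01, 1.44, 1.17 and 0.264 TPM. Cd34 was thus 65.6-fold above Pecam1 and 91.4-fold above Pdgfra. Ly6a, which encodes the excluded marker SCA1, was higher than those 4 genes, at 16.4 TPM. The related gene Ly6e stood at 52.5 TPM. Xist, the RNA that silences an X chromosome in female cells, stood at 142 TPM. The Y-linked genes Kdm5d and Uty were at 0.0371 and 0.0111 TPM, and Ddx3y and Eif2s3y were listed at 0.

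Basal keratinocyte genes were the highest of the lineage lists, and genes of differentiating cells were lower but detected. The 10 basal genes had a median of 107 TPM, led by Krt5 at 3833 TPM and Krt14 at 1464 TPM. The others were Trp63 at 162 TPM, Itgb1 at 135 TPM, Thbs1 at 78.7 TPM, Itgb4 at 72.8 TPM, Ptn at 65.9 TPM and Ly6d at 43.1 TPM, with Col17a1 and Ly6a as given above. Of 25 suprabasal epidermal genes, 21 reached 1 TPM, with a median of 7.58 TPM over all 25. Krtdap at 769 TPM and Sbsn at 359 TPM led that list, while the suprabasal keratins Krt10 and Krt1 stood at 138 and 33.0 TPM. Krt15 was 24.3-fold above Krt10 and 101.8-fold above Krt1. Fabp5 stood at 110.1 TPM, and the late cornification genes Lce1a1 and Flg were lowest at 0.443 and 0.00794 TPM. Of 26 inner root sheath, matrix and hair shaft genes, 24 reached 1 TPM, with a median of 8.37 TPM. The highest were the inner root sheath keratin gene Krt71 at 51.3 TPM, Hoxc13 at 40.0 TPM, Gata3 at 38.2 TPM and Krt25 at 38.2 TPM, and the lowest were Krt34 at 0.409 TPM and Krtap3-1 at 0.138 TPM. Krt15 was 65.5-fold above Krt71. Among 19 upper follicle and sebaceous genes, Defb6 at 283 TPM, Krt79 at 107 TPM, Mgst1 at 93.7 TPM and Lrig1 at 93.0 TPM were highest, and Awat1 and Scd3 were lowest at 0.271 and 0.211 TPM. In the list for the inner bulge and companion layer, Krt17 stood at 1680 TPM, Timp3 at 282 TPM, Krt6a at 73.9 TPM, Krt75 at 17.6 TPM, Krt16 at 2.65 TPM and Krt6b at 0.332 TPM. Krt6a and Krt6b are near-identical copies, so the split of their reads is uncertain.

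**Figure D1:**
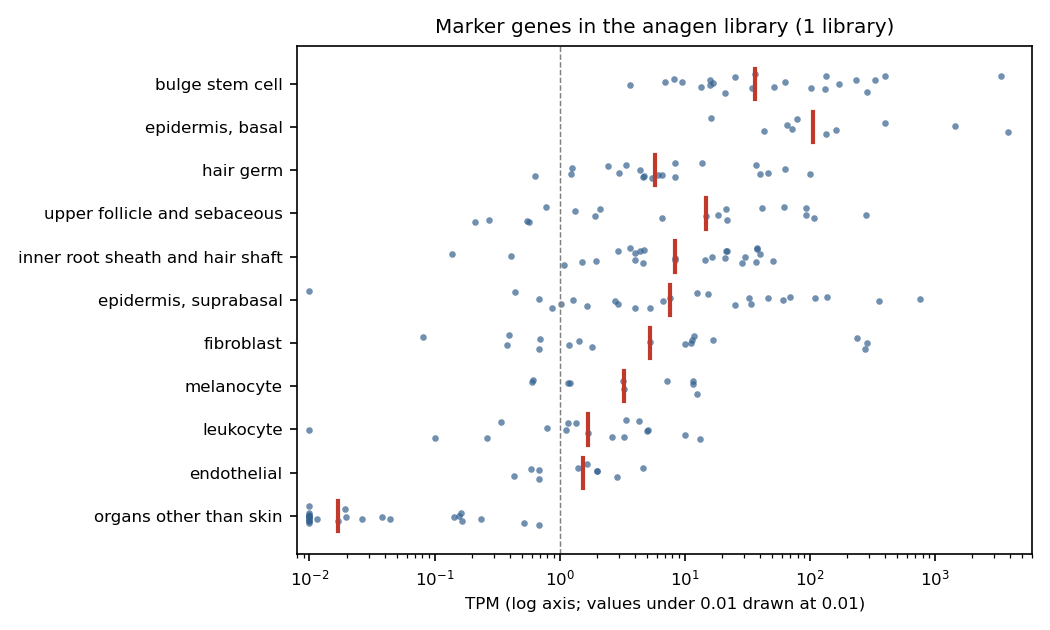
TPM of the listed marker genes of each cell type in the 1 anagen library, on a log axis; each point is a gene, the red bar is the list's median over all members and the dashed line is 1 TPM. Medians run from 107 TPM for basal epidermal genes and 36.7 TPM for bulge genes to 1.54 TPM for endothelial genes and 0.0168 TPM for genes of organs other than skin. The fibroblast row also holds dermal papilla genes.

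Hedgehog pathway genes were detected at levels that ranged widely. Shh, of which the animals carry 1 functional copy, stood at 1.26 TPM (ENSMUSG00000002633, chromosome 5, 28456840 to 28467101). As both samples share the genotype, this value does not test the label. Gli1, a direct target of hedgehog signalling, was 36.6-fold higher at 46.1 TPM, and the receptor gene Ptch1 stood at 25.0 TPM. The co-receptor gene Gas1 led the list at 91.8 TPM, followed by the signal transducer Smo at 59.6 TPM. The other ligand genes, Dhh and Ihh, were lowest at 0.247 and 0.0814 TPM. In all, 13 of 15 hedgehog genes reached 1 TPM, and the median of those 13 lay at the 37.0th percentile of random lists. The list lay at 75.5% with no filter on low values and at 66.0% among genes at 5 TPM or more. It was neither high nor low in any setting.

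Genes of the Wnt pathway ranged widely. Of 35 listed, 28 reached 1 TPM, and their median of 7.12 TPM exceeded that of 2.43% of random lists. Under the 6 other settings tried, this position was between 3.02% and 44.4%, so the list was not low in any of them. The highest were Ctnnb1, which encodes beta-catenin, at 347 TPM, the antagonist Sfrp1 as above, Ccnd1 at 83.4 TPM and the receptor Fzd7 at 66.1 TPM. Lgr5 stood at 63.9 TPM, Axin2 and Lef1 stood at 5.48 and 4.75 TPM, and Wnt3a and Wnt7a were lowest at 0.0519 and 0.0111 TPM. The 20 hair germ genes had a median of 5.78 TPM, led by Cdh3, the P-cadherin of the hair germ, at 99.7 TPM, Lgr5 and Gli1 as above and Hoxc13 at 40.0 TPM, with Wnt10b at 1.23 TPM and Edar at 0.634 TPM lowest. Among BMP and TGF-beta genes, 27 of 29 reached 1 TPM. The BMP target genes Id3, Id2 and Id1 were at 133, 87.2 and 69.6 TPM and Smad4 at 44.4 TPM, while Bmpr1b was lowest at 0.0958 TPM. Of 16 Notch pathway genes, 12 reached 1 TPM, with Jag2 at 86.6 TPM, Notch1 at 84.1 TPM, Hes1 at 59.3 TPM and Lfng at 52.7 TPM highest and Dll4 and Mfng at 0.144 and 0.111 TPM lowest.

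Every listed G1/S and G2/M gene was expressed in the anagen library. All 32 G1/S genes and all 35 G2/M genes were above 5 TPM, with medians of 24.0 and 19.4 TPM. These medians exceeded those of 98.8% and 95.1% of random lists, and those of 85.8% and 60.3% when only genes at 5 TPM or more were kept. The replication genes Pcna, Mcm6, Slbp and Gins2 stood at 75.3, 63.3, 61.2 and 56.8 TPM, and Cdc6 was lowest at 6.06 TPM. Among mitotic genes, Top2a stood at 98.3 TPM, Cks2 at 88.5 TPM, Ube2c at 80.6 TPM and Cdk1 at 70.9 TPM. Mki67 and Ccnb1 stood at 34.0 and 27.4 TPM, and Cenpe and Kif20b were lowest at 6.05 and 5.97 TPM. The inhibitors Cdkn1b and Cdkn1a were at 49.1 and 31.9 TPM, Cdkn2c and Cdkn2d at 22.5 TPM each, and Cdkn2a at 0.135 TPM. These values are averages over the sorted cells and do not give a share of cycling cells.

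The series title names the integrated stress response, in which phosphorylation of eIF2 lowers translation and raises ATF4, and serine deprivation. The anagen sample is titled a control, and its levels were not compared with any stressed or serine-deprived sample. Of 52 stress response effectors and ATF4 target genes, 48 reached 1 TPM, and their median of 20.5 TPM exceeded that of 98.5% of random lists. It was 89.95% when only genes at 5 TPM or more were kept. The amino acid transporter gene Slc3a2 was highest at 279 TPM, followed by Atf4 at 127 TPM (ENSMUSG00000042406, chromosome 15, 80255184 to 80257545), Cebpb at 114 TPM and Ddit4 at 109 TPM. The pro-apoptotic factor Ddit3, which encodes CHOP, stood at 20.1 TPM, the asparagine synthetase gene Asns at 16.1 TPM and Sesn2 at 5.76 TPM. Chac1 and Trib3 were at 0.610 and 0.394 TPM. Aldh1l2 and Gdf15 were also under 1 TPM, at 0.419 and 0.735 TPM. These are RNA levels of 1 library. They measure neither eIF2 phosphorylation nor ATF4 protein, so they do not show whether the response was active. All 20 cytosolic aminoacyl-tRNA synthetase genes were above 10 TPM, with a median of 26.7 TPM, from Qars at 108 TPM, Vars at 63.0 TPM, Sars at 57.9 TPM and Kars at 35.2 TPM down to Lars at 14.6 TPM and Iars at 12.9 TPM. Their median exceeded that of 98.5% of random lists, and of 89.6% when only genes at 5 TPM or more were kept. Many of these synthetase genes, Sars and Iars among them, also belong to the stress response list, so the lists are not independent.

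All 17 genes of the eIF2 machinery were detected, with a median of 19.0 TPM. This median exceeded that of 86.3% of random lists, neither high nor low. The position was 57.45% among genes at 5 TPM or more and 98.4% with no filter on low values. The phosphatase gene Ppp1cc led at 117 TPM, on a gene ID that the table also assigns to the copy Ppp1ccb. The eIF2 subunit genes Eif2s3x and Eif2s2 followed at 55.6 and 43.4 TPM, and the eIF2B subunit gene Eif2b2 at 37.7 TPM. The 4 eIF2 kinase genes were lower. Eif2ak1, the heme-regulated kinase, stood at 11.4 TPM, Eif2ak4, the amino acid sensor GCN2, at 6.26 TPM, Eif2ak2, the kinase PKR, at 4.65 TPM and Eif2ak3, the endoplasmic reticulum kinase PERK, at 3.87 TPM.

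The 3 enzymes that make serine from a glycolytic intermediate were expressed at similar levels. Phgdh stood at 43.3 TPM (ENSMUSG00000053398, chromosome 3, 98313171 to 98339969). Psph stood at 34.9 TPM (ENSMUSG00000029446, chromosome 5, 129765558 to 129787443) and Psat1 at 33.4 TPM (ENSMUSG00000024640, chromosome 19, 15905123 to 15925059). Each was above the 12.5 TPM median of expressed protein-coding genes, and Phgdh was 1.30-fold above Psat1. The median of the 3 enzymes exceeded that of 88.5% of random lists, or 80.3% among genes at 5 TPM or more. By the rule used here this list was neither high nor low. In the wider list of serine, glycine and folate metabolism, 36 of 38 genes reached 1 TPM, and their median of 17.7 TPM exceeded that of 91.3% of random lists. Its highest members were Gnmt, which methylates glycine, at 348 TPM, Mat2a, which makes S-adenosylmethionine, at 268 TPM, Cbs at 137 TPM and Paics at 83.5 TPM. The cytosolic enzymes Shmt1 and Mthfd1 stood at 40.2 and 34.3 TPM, against 23.2 and 10.8 TPM for their mitochondrial counterparts Shmt2 and Mthfd2. Gldc, of the mitochondrial glycine cleavage system, was lowest at 0.125 TPM. Phgdh, Psat1, Psph, Shmt2 and Mthfd2 also belong to the stress response list, so these lists overlap as well.

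**Figure D2:**
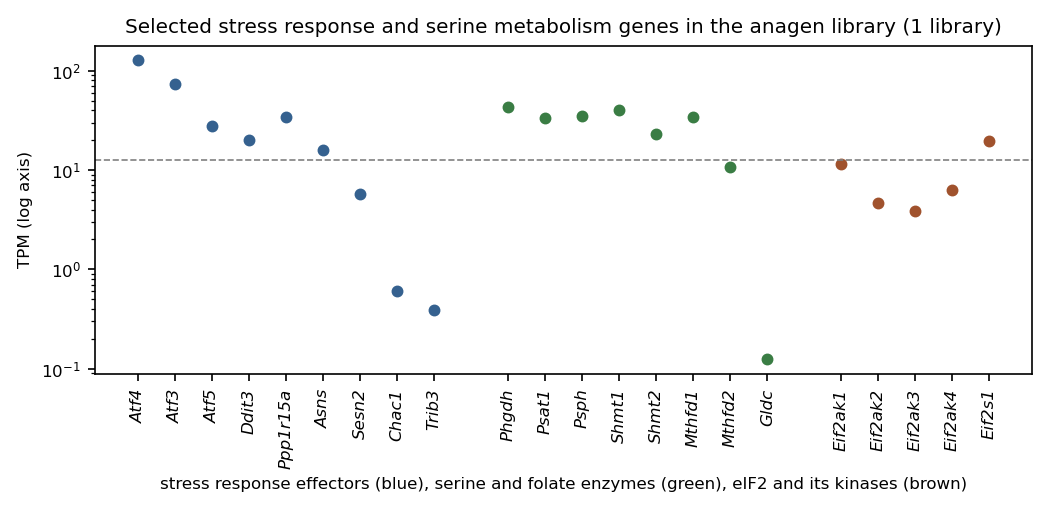
TPM, on a log axis, of selected genes of the stress response, of serine and folate metabolism and of eIF2 and its kinases in the 1 anagen library; each point is a gene and the dashed line is the median of protein-coding genes at 1 TPM or more, 12.5 TPM. Of the genes drawn, Atf4 at 127 TPM is the highest, and Trib3, Chac1 and Gldc lie under 1 TPM.

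Among other metabolic and stress lists, those of the respiratory chain, glycolysis, heat shock genes and immediate early genes were among the ones with high medians. Respiratory chain and ATP synthase subunits had a median of 146 TPM over 44 genes, led by Atp5b at 600.1 TPM, Cox4i1 at 506 TPM, Cox6a1 at 407 TPM and Atp5g3 at 402 TPM, with Cycs and Ndufa9 lowest at 38.9 and 36.5 TPM. Of 22 glycolysis genes, 21 reached 1 TPM, and the median over all 22 was 52.8 TPM. Gapdh at 352 TPM, Pkm at 272 TPM, Ldha at 256 TPM and Aldoa at 184 TPM were highest. The lactate exporter Slc16a3 was lowest at 0.740 TPM. The 22 immediate early genes, which cell isolation can induce, had a median of 84.2 TPM, with Fos at 237 TPM, Jun at 233 TPM, Egr1 at 219 TPM and Btg2 at 148 TPM. The 12 cytosolic heat shock genes had a median of 202 TPM, with Hspb1 at 775 TPM, Hsp90ab1 at 744 TPM, Hspa1b at 655 TPM and Hspa8 at 558 TPM. Hspa1b and Hspa1a are near-identical, so reads may be split between them. No random list of the same size had a median as high as the respiratory, immediate early, heat shock or ribosomal protein list. The same held for the glycolysis genes at 1 TPM or more. Atf3, which belongs to both the stress response and the immediate early list, stood at 74.1 TPM. Genes of the unfolded protein response and of endoplasmic reticulum chaperones had a median of 26.5 TPM over all members. Hspa5 at 316 TPM, Calr at 286 TPM, Hsp90b1 at 265 TPM and Pdia3 at 256 TPM were highest. The median of the members at 1 TPM or more exceeded that of 98.7% of random lists. The list lay at 95.35% among genes at 5 TPM or more. The 8 mitochondrial chaperone and protease genes had a median of 26.5 TPM, led by Hspe1 at 216 TPM. Cholesterol synthesis genes had a median of 18.9 TPM, above 90.1% of random lists at 1 TPM or more. That position was 63.7% among genes at 5 TPM or more and 99.0% with no filter on low values. Antioxidant genes had a median of 33.7 TPM, above 99.2% of random lists, or 97.4% by the mean of the log2 values. The 26 ribosome biogenesis genes had a median of 20.8 TPM and the 44 ribosomal protein genes one of 933 TPM. Many ribosomal protein genes have processed pseudogene copies, so their single values are uncertain.

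Matrix and adhesion genes were high, and the members of the wound and interferon lists ranged widely. The 20 basement membrane and niche genes had a median of 97.1 TPM, with Col17a1, Postn, Col18a1 at 186 TPM and Col4a1 at 157 TPM highest. Of 27 genes linked to wound response, 19 reached 1 TPM, with Krt17, Tnc at 99.3 TPM and Itga3 at 85.2 TPM among the highest. The median of those 19 exceeded that of 99.0% of random lists. Yet the position was 20.5% with no filter on low values and 77.8% after rescaling without mitochondrial and the 50 highest genes. It was 85.6% by the mean of the log2 values. Mmp13 was at 0.0134 TPM and Mmp10 was listed at 0. Of 18 interferon response genes, 13 reached 1 TPM, led by the antigen presentation genes B2m at 153 TPM, H2-D1 at 145 TPM and H2-K1 at 85.4 TPM and by Ifitm3 at 68.2 TPM.

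Genes of other skin cells were present, most lists of them with a lower median than the bulge genes and the globin list with a higher one, 45.5 TPM. Of 17 fibroblast and dermal papilla genes, 12 reached 1 TPM. The fibrillar collagen genes Col3a1, Col1a1 and Col1a2 stood at 287, 278 and 237 TPM, followed by Col6a3 at 17.0 TPM. The melanocyte genes Mlana, Dct, Pmel and Tyrp1 stood at 12.6, 11.7, 11.6 and 7.21 TPM, and Slc45a2 and Sox10 at 0.618 and 0.602 TPM. Leukocyte genes had a median of 1.70 TPM, and the median of the 12 above 1 TPM exceeded that of 0.24% of random lists, or 12.2% with no filter on low values, with Cd74 at 13.2 TPM, Lyz2 at 10.02 TPM, C1qa at 5.11 TPM and H2-Ab1 at 5.002 TPM highest. Endothelial genes had a median of 1.54 TPM, and the median of the 6 above 1 TPM exceeded that of 0.08% of random lists, or 12.97% with no filter, with Plvap highest at 4.65 TPM. Schwann and Merkel cell genes had a median of 2.26 TPM, with Pmp22 at 47.0 TPM, Krt8 at 9.26 TPM and S100b at 6.02 TPM among the highest. The globin genes Hbb-bs, Hba-a2, Hba-a1 and Hbb-bt stood at 99.6, 54.0, 45.5 and 12.1 TPM, where the Hba pair are near-identical copies. Of 10 muscle and adipocyte genes, Acta2 and Fabp4 were at 254 and 12.5 TPM and the other 8 were under 1 TPM.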

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

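Over 6 alternative settings, 203 of 244 list percentiles kept their call as high, low or neither, and none went from high to low or from low to high. A list called neither can move far and keep that call. The BMP and TGF-beta list, for example, went from 25.5% to 82.7% with no filter on low values. The Wnt list, low in the main setting at 2.43%, was not low in any of the 6. It lay at 44.4% with no filter on low values, 35.2% at 5 TPM or more, 4.71% after rescaling without mitochondrial and the 50 highest genes, 38.6% by the mean, 4.30% with all named genes as background and 3.02% without ribosomal and mitochondrial genes in the background. The last 2 settings were chosen after seeing the data. At 5 TPM or more, the G1/S list went from 98.8% to 85.8% and the stress response list from 98.5% to 89.95%. The G2/M list went from 95.1% to 60.3%, the tRNA synthetase list from 98.5% to 89.6% and the quiescence list from 98.8% to 94.7%. All genes of the G1/S, G2/M and tRNA synthetase lists are above 5 TPM, so for these the setting changed only the background. With no filter, the G2/M list went from 95.1% to 99.9% and the one-carbon list from 91.3% to 99.7%. As every G2/M gene is above 5 TPM, dropping the filter also changed only the background for that list. By the mean of the log2 values, the G2/M list stood at 99.1%. For the other shifts, the cause was not tested. The hair germ list, low at 2.16%, lay between 3.54% and 47.0% in 5 settings. Rescaling multiplied every other gene by 1.73, so the levels printed as TPM depend on it while ratios between genes do not. The number of genes called detected was 14452 at 1 TPM, 24251 above 0 and 10347 at 5 TPM. Settings foreseen before the data were examined on pseudocounts, on 2-fold and 3-fold differences, on scaling of 2 libraries to each other, on values in both libraries, on bins of matched lists and on the correlation of libraries were not run, since they need a second library. No replicate could be left out. The unknown read depth limits what can be said of genes under about 1 TPM.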

Other observations

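Outside the listed groups, several nuclear protein-coding genes stood among the most abundant. Ucp2, an inner mitochondrial membrane carrier, stood at 4636 TPM, and Apoe, a lipid transport protein, at 4571 TPM, both above Krt5 and Krt15. Lgals7, a galectin of stratified epithelia, stood at 2037 TPM. These genes were named after their values were seen.

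Of the tests that follow, the one on mitochondrial genes was chosen only after the result was seen. Transcripts of skin cells that the sort should remove were present in the anagen library. The median over all listed genes was 5.30 TPM for fibroblasts and dermal papilla together and 3.26 TPM for melanocytes. It was 1.70 TPM for leukocytes and 1.54 TPM for endothelial cells. Within the fibroblast and dermal papilla list, Col3a1, Col1a1 and Col1a2 stood far above its median, at 287, 278 and 237 TPM. The bound of 1 TPM set in advance for such cells does not separate them from chance, since the median of all protein-coding genes was 2.44 TPM. Carry-over of these cells or their RNA and expression by the stem cells themselves therefore both stay open. Reads spread over genes of every tissue are argued against: 25 genes of organs other than skin had a median of 0.0168 TPM and none reached 1 TPM. No biological explanation was tested.

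Genes that lie on the same mitochondrial RNA had different TPM. mt-Atp8, 204 bases long, stood at 112904 TPM, or 10.3-fold above mt-Atp6, which is 681 bases long and overlaps it. mt-Nd4l, 297 bases, was 3.18-fold above mt-Nd4, 1378 bases. The short mt-Nd3, 348 bases, stood at only 2419 TPM. Across the 13 protein genes of the mitochondrial genome, which are not independent replicates, Spearman's rho of length and TPM was -0.456. Whether TPM is inflated for features shorter than a read pair stays open, since the 2 gene pairs prompted the idea and most of the other genes are long. mt-Atp8 alone was 11.3% of the library's TPM.

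Rps27rt, a retrogene copy of Rps27, was listed as the highest nuclear protein-coding gene at 5060 TPM, 1.48-fold above Rps27. The split of reads between a gene and its copy is uncertain, so this rank and this ratio are uncertain too. The split was not tested.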
